A study of Homo sapiens with 12 samples.

How the data were processed

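T47D cells, a hormone-receptor-positive human breast cancer line, were held for 24 h with ethanol vehicle, estradiol (E2), the synthetic progestin R5020, or both hormones together, in medium with 5% serum. Total RNA was sequenced as standard Illumina libraries, with 3 replicate libraries in each of 4 groups. The deposited values are raw read counts per gene symbol for 12 libraries. Per the submitters' processing notes, cutadapt, STAR, SAMtools, DESeq2 and the GRCh38 build were used. Versions, the counting tool, its strand setting, the annotation release and the treatment of reads that map to several places were not given in the sources used here.

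The missing counting details bear on the measurements. Reads from near-identical or closely related genes, such as the alpha-globin genes HBA1 and HBA2, the AKR1C family, KRT6A and its neighbours, or histone genes, could have been split or dropped, so values of single members are uncertain. Without a stated strand setting, reads from a gene and its antisense partner cannot be separated. The table held 44 symbols made unique with a suffix; H19_2 is one of them and was not matched to a position. Coordinates are 1-based spans of the genes in the GENCODE annotation on GRCh38, which may differ from the release used for counting; 132 of the 135 genes named by the rule and reported were placed.

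From the deposited counts, genes were kept with edgeR's filterByExpr (minimum count of 10, by group), which left 17753 of 56505 symbols; 26306 symbols had no count in any library. The kept genes held over 99.9% of each library's counts. Library sizes were scaled with TMM factors. All 12 libraries entered one edgeR (version 4.0.16, R 4.3.3) quasi-likelihood model with a mean per group, so that every comparison shared one estimate of the spread. Log2 fold changes are given with a standard error taken from the quasi-likelihood F statistic, and p-values were adjusted with the Benjamini-Hochberg method within each of 7 comparisons, at a threshold of 0.05. The seventh comparison is the interaction, which is the R5020 effect in E2-treated cells minus the R5020 effect in vehicle-treated cells. The design, the gene lists, the rule for named genes and the alternative settings were written before the data were examined, except where stated.

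The 22 gene lists, with 457 members in all, were tested with camera (limma version 3.58.1) at a preset correlation between genes of 0.01. The camera test compares a list's genes with all other tested genes. It was repeated with a correlation estimated from the data, and with fry, which asks whether a list's genes move one way on balance and makes no comparison with other genes. A list needed 5 tested members, which 21 lists had. In each comparison p-values were adjusted over the lists. Members were counted as risen or fallen by their own adjusted p over all tested genes, and again with p-values adjusted over the list alone.

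Named genes were, in each comparison, the 6 largest changes in either direction among genes with a mean log2 CPM of at least 1 and libraries that did not overlap (the last condition was dropped for the interaction), the 3 members with the smallest adjusted p in each list that passed the camera test, and a fixed set of hormone-related genes (PGR, ESR1, TFF1, GREB1, FKBP5, ELF5, TNFSF11, KRT5, MYC, CCND1 and MKI67 among them). Some genes that the rule names are not reported here. A gene named under one comparison was not always repeated under another. TNFSF11 had at most 4 counts in a library and was not tested.

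Total counts per library ran from 27587606 to 38594558. The test was tried on simulated counts for 17355 genes that passed the filter, with the real library sizes, means in vehicle and dispersions. For E2 vs vehicle it recovered 59.7% of 67 genes simulated with a 1.25-fold change. It recovered 67.2% of 67 with 1.5-fold and 80.3% of 66 with 2-fold, and 4.83% of its calls were false. That is far fewer changed genes than the 6053 called for E2 in the data. With few changed genes the Benjamini-Hochberg adjustment is stricter, so these shares do not give the recovery for E2 in the data. For the interaction the shares were 37.3%, 56.7% and 72.7%, with 5.13% false calls. Replicate libraries differed by a chi-square per degree of freedom of 2.36 to 16.3, above the value of 1 that counting error alone gives.

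E2 vs vehicle and R5020 vs vehicle share their vehicle libraries, so 100 simulated sets of unchanged groups were drawn to show how far their fold changes correlate with no effect at all. The alternatives tried were other normalization factors, other filters on low counts, DESeq2 (version 1.42.0), limma-voom, the replicate number as a block, only the compared groups in the model, stricter thresholds, and each library left out in turn. Added after seeing the data were removal of rDNA-repeat and mitochondrial genes, and upper-quartile factors for the gene lists. Figures were drawn with matplotlib under Python. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.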

Results

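Transcript levels were measured in T47D breast cancer cells after 24 h with vehicle, E2, R5020 or E2+R5020, with 3 libraries per group. The libraries held 27587606 to 38594558 counts. The first principal component, with 37.3% of the variance, parted the 6 libraries with E2 from the 6 without. The second, with 19.2%, parted libraries with R5020 from those without, and the vehicle libraries differed along it, at 12.7, 19.8 and 4.27 for replicates 1, 2 and 3, against -8.51 to -11.5 for R5020. Replicate 3 of vehicle also differed most from the others in its counts: the chi-square per degree of freedom was 16.3 and 15.7 against vehicle replicates 1 and 2, which differed from each other by 3.42. Genes of the rDNA repeat took 3.88% of counts in vehicle replicate 3, 6.63% in replicate 1 and 6.20% in replicate 2. These abundant genes weigh heavily on that chi-square, which was not computed without them. It therefore does not show a difference spread over many genes. Counts of changed genes are therefore also given without vehicle replicate 3.

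**Figure D1:**
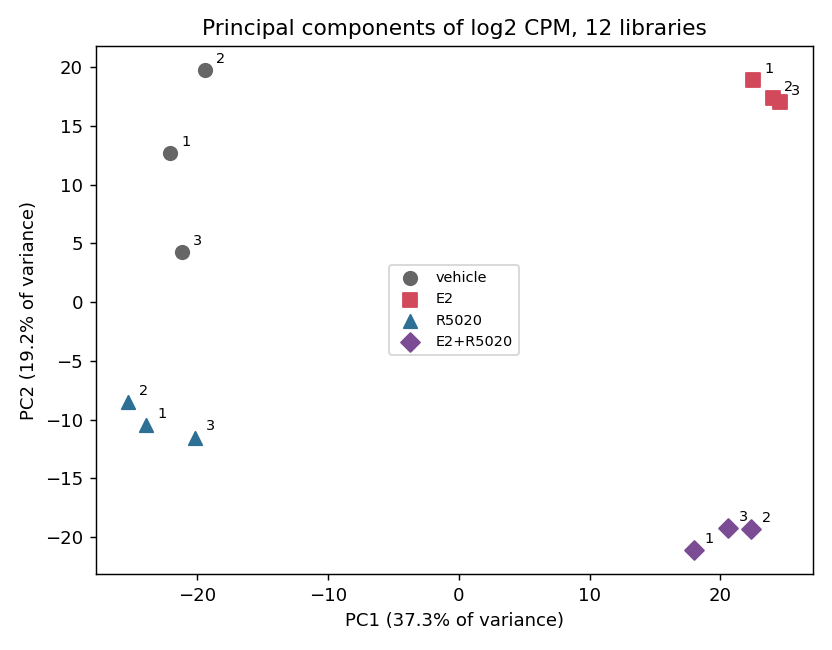
Principal component scores of the 12 libraries from log2 CPM, with PC1 on the x axis and PC2 on the y axis; symbols mark the 4 groups and digits the replicate. Libraries with E2 lie to the right and libraries with R5020 lie low, and vehicle replicate 3, at 4.27 on PC2, lies nearest to the R5020 libraries.

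E2 vs vehicle asks what estrogen alone changes. E2 raised the progesterone receptor gene PGR from 91.5 ± 2.87 to 483 ± 12.6 CPM (SD, n = 3), a log2 fold change of 2.40 ± 0.04 (SE; edgeR adjusted p = 1.01e-27). The chemokine gene CXCL12 rose by 3.00 ± 0.09, from 3.09 ± 0.254 to 24.7 ± 1.03 CPM (SD, n = 3), while CXCR4, which encodes the receptor of that chemokine, fell, with a log2 fold change of -2.02 ± 0.08. MYC rose by 1.63 ± 0.05, the cell cycle gene CCND1 by 0.42 ± 0.04 and ESR1, which encodes estrogen receptor alpha, by 0.36 ± 0.04. The luminal transcription factor gene ELF5 changed by -0.41 ± 0.03 and the basal keratin gene KRT5 by -1.36 ± 0.19, both lower with E2. Among genes that met the conditions on level and overlap, the other largest rises were in GATA4 (4.67 ± 0.29), SPINK4 (3.83 ± 0.24), CHRM4 (2.74 ± 0.12) and CISH (2.40 ± 0.10). GATA4 and SPINK4 had a mean log2 CPM of only 1.04 and 1.11 over the 12 libraries, against a minimum of 1 for naming. Their levels without E2 were therefore low, here and in the later comparisons that name them. The other largest falls were in TM4SF1 (-2.83 ± 0.20), CHST1 (-2.63 ± 0.13), EDN2 (-2.16 ± 0.15), NWD1 (-2.07 ± 0.17) and PCDH17 (-1.83 ± 0.23). FKBP5 at -0.10 ± 0.04 and the proliferation marker MKI67 at -0.01 ± 0.04 did not pass the threshold (adjusted p = 0.0598 and 0.889). TFF1, an estrogen target, had only 3 to 20 counts in a library, and its value of 0.98 ± 0.41 did not pass (adjusted p = 0.066).

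Of 28 estrogen receptor targets, 25 rose and 0 fell (26 rose when adjusted over the list alone), with a median log2 fold change of 1.01. For estrogen receptor targets the camera test gave adjusted p = 4.38e-90, and adjusted p = 6.87e-06 with an estimated correlation. RAPGEFL1 rose by 1.70 ± 0.04, CA12 by 1.28 ± 0.03 and GREB1 by 1.09 ± 0.05. All 18 ribosome biogenesis genes rose, also when adjusted over the list alone, with a median of 0.47. For ribosome biogenesis genes the camera test gave adjusted p = 2.45e-23, and adjusted p = 0.00241 with an estimated correlation; NOP56 rose by 0.68 ± 0.03, NOLC1 by 0.55 ± 0.03 and RRP12 by 0.47 ± 0.04. Of 29 genes of DNA replication and the G1/S transition, 19 rose (22 adjusted over the list alone), MCM10 by 0.50 ± 0.04, E2F1 by 0.36 ± 0.04 and MCM2 by 0.32 ± 0.04; the median was 0.14. For DNA replication and G1/S genes the camera test gave adjusted p = 3.49e-05, but adjusted p = 0.783 with an estimated correlation. Of 19 cytosolic ribosomal protein genes, 12 rose (14 adjusted over the list alone), RPL19 by 0.18 ± 0.04, RPL35 by 0.17 ± 0.04 and RPS23 by 0.16 ± 0.04; this list passed at adjusted p = 0.0378, and not with an estimated correlation (adjusted p = 0.783), upper-quartile factors or without vehicle replicate 1, vehicle replicate 3, E2 replicate 2 or E2 replicate 3. Of these ribosomal protein genes 3 rose without E2 replicate 3 and 5 with upper-quartile factors. Of 23 interferon-stimulated genes, 14 fell (15 adjusted over the list alone), IRF7 (-0.75 ± 0.12), DDX58 (-0.57 ± 0.12) and STAT2 (-0.53 ± 0.06) among them, with a median of -0.54. For interferon-stimulated genes the camera test gave adjusted p = 0.00247, but adjusted p = 0.783 with an estimated correlation. The number of these genes that fell was 7 without vehicle replicate 2, and 5 of 22 tested in DESeq2. The call of the list also ended without vehicle replicate 2: the list's mean per library, relative to the vehicle mean, was -0.05, 0.47 and -0.41 in vehicle and -0.08, -0.94 and -0.66 with E2.

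In all, 6053 genes changed with E2, of which 3237 were higher and 2816 lower, and 430 changed at least 2-fold. With upper-quartile factors the split turned to 2675 higher and 3504 lower, with a shift of the median of all genes of -0.03 on the log2 scale, so the balance of small changes depends on the scaling. Without vehicle replicate 3 the count was 5422.

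R5020 vs vehicle asks what the progestin alone changes. R5020 raised SLPI, a secreted protease inhibitor, from 3.49 ± 2.09 to 12.3 ± 0.305 CPM (SD, n = 3), a log2 fold change of 1.81 ± 0.18 (SE; edgeR adjusted p = 1.37e-07). KRT5 rose from 20 ± 9.63 to 43.5 ± 4.06 CPM, by 1.11 ± 0.15, with a wide spread among the vehicle libraries. The water channel gene AQP3 fell from 135 ± 29.2 to 81 ± 2.87 CPM, with a log2 fold change of -0.74 ± 0.08, and the keratin gene KRT4 with one of -1.12 ± 0.13. The desmosomal gene PKP1 rose by 1.68 ± 0.16, SERPINE2 by 1.60 ± 0.23, ELFN2 by 1.53 ± 0.20, HBA2 by 1.51 ± 0.14 and PLCB2 by 1.48 ± 0.21; HBA2 has a near-identical copy and its value is uncertain. CORO2B (-0.87 ± 0.08), AMPH (-0.71 ± 0.13), TMEM52B (-0.68 ± 0.16) and BCL2 (-0.63 ± 0.16) fell, the last of them not past the threshold without vehicle replicate 2 or R5020 replicate 3. FKBP5 rose by 0.18 ± 0.04, GREB1 by 0.24 ± 0.05 and CCND1 by 0.17 ± 0.04. PGR (0.05 ± 0.04), MYC (0.14 ± 0.06), ESR1 (0.13 ± 0.04), MKI67 (-0.08 ± 0.04), ELF5 (-0.01 ± 0.03) and TFF1 (-0.13 ± 0.47) did not pass (adjusted p = 0.0634 or above).

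Of 26 progestin receptor targets, 9 rose and 0 fell (14 and 1 adjusted over the list alone), SGK1 by 0.66 ± 0.07 and KLF4 by 0.43 ± 0.06. For progestin receptor targets the camera test gave adjusted p = 2.89e-07, but adjusted p = 0.0996 with an estimated correlation. Of 29 DNA replication and G1/S genes, 22 fell (26 adjusted over the list alone), with a median of -0.19; CDC6 fell with a log2 fold change of -0.30 ± 0.05, GINS1 of -0.24 ± 0.04 and PCNA of -0.20 ± 0.03. For DNA replication and G1/S genes the camera test gave adjusted p = 1.58e-25, but adjusted p = 0.0996 with an estimated correlation. Hypoxia and glycolysis genes rose in 7 of 17 cases and fell in 1 (8 and 1 adjusted over the list alone), ALDOA by 0.28 ± 0.04, LDHA by 0.28 ± 0.03 and VEGFA by 0.25 ± 0.04. For hypoxia and glycolysis genes the camera test gave adjusted p = 2.89e-07, but adjusted p = 0.121 with an estimated correlation. In steroid receptors and steroid metabolism 5 of 16 genes rose (8 rose and 1 fell adjusted over the list alone), CYP1A1 by 0.82 ± 0.08 and the related AKR1C2 and AKR1C3 by 1.18 ± 0.17 and 1.48 ± 0.24. For steroid receptors and steroid metabolism the camera test gave adjusted p = 2.78e-06, but adjusted p = 0.0996 with an estimated correlation. Without vehicle replicate 3 the genes of this list that rose numbered 8. Fatty acid and triglyceride genes rose in 6 of 20 cases (6 rose and 1 fell adjusted over the list alone), ACSL1 by 0.29 ± 0.04, SREBF1 by 0.17 ± 0.03 and ELOVL5 by 0.17 ± 0.03. For fatty acid and triglyceride genes the camera test gave adjusted p = 0.00258, but adjusted p = 0.0996 with an estimated correlation.

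Basal and myoepithelial markers rose in 3 of 14 cases and fell in 1, the same numbers adjusted over the list alone; beside KRT5 these were KRT6A (1.35 ± 0.17) and CD44 (0.39 ± 0.05), and the list passed at adjusted p = 0.00228, but not with an estimated correlation (adjusted p = 0.268). The marker that fell was lost without vehicle replicate 2, R5020 replicate 2 or R5020 replicate 3. Interferon-stimulated genes fell in 4 of 23 cases (11 adjusted over the list alone), MX1 (-0.75 ± 0.20), IFIH1 (-0.50 ± 0.13) and BST2 (-0.20 ± 0.05) among them. For interferon-stimulated genes the camera test gave adjusted p = 8.77e-07, but adjusted p = 0.503 with an estimated correlation, and all of these 3 were lost without vehicle replicate 2 or R5020 replicate 1. The interferon-stimulated genes that fell numbered 0 without either of these libraries, 0 of 21 tested in DESeq2, 2 with only the compared groups in the fit, and 14 without vehicle replicate 3, without R5020 replicate 3 or without a filter. Antigen presentation genes fell in 2 of 11 cases (5 adjusted over the list alone), PSMB9 (-0.61 ± 0.14) and PSMB8 (-0.37 ± 0.11), the latter lost without either of vehicle replicates 1 and 2 or R5020 replicates 1 and 2, while 5 fell without vehicle replicate 3; TAPBP was at -0.10 ± 0.03. For antigen presentation genes the camera test gave adjusted p = 3.02e-04, but adjusted p = 0.425 with an estimated correlation. Mitosis genes fell in 3 of 25 cases (8 adjusted over the list alone), FOXM1 (-0.13 ± 0.03), TOP2A (-0.12 ± 0.04) and NUSAP1 (-0.10 ± 0.03), each lost under several left-out libraries, and with a median of only -0.06. For mitosis genes the camera test gave adjusted p = 3.48e-04, but adjusted p = 0.537 with an estimated correlation. The mitosis genes that fell numbered 0 without vehicle replicate 1, without R5020 replicate 1 or with only the compared groups in the fit, and 6 without vehicle replicate 2 or in DESeq2. None of 13 mitochondrially encoded mRNAs passed in edgeR, also adjusted over the list alone, against 1 each in DESeq2 and limma-voom and 4 without a filter; MT-ND2 (-0.13 ± 0.05), MT-ND1 (-0.13 ± 0.05) and MT-ATP8 (-0.11 ± 0.05) had the smallest adjusted p. Their list median was -0.08. For mitochondrially encoded mRNAs the camera test gave adjusted p = 0.00155, but adjusted p = 0.537 with an estimated correlation, and the call ended without R5020 replicate 3, in which these mRNAs took 11.6% of counts against 13.1% and 13.0% in replicates 1 and 2. Nuclear and non-polyadenylated RNAs rose in 3 of 11 cases (4 adjusted over the list alone), NEAT1 (0.28 ± 0.07), HIST1H2AC (0.32 ± 0.06) and MALAT1 (0.15 ± 0.05); the list passed at adjusted p = 0.0213, but not with an estimated correlation (adjusted p = 0.503) or without vehicle replicate 3, R5020 replicate 1 or R5020 replicate 2, NEAT1 was lost without vehicle replicate 2 or R5020 replicate 1, and MALAT1 under 14 of the settings tried, and 1 gene of the list rose without vehicle replicate 2 or R5020 replicate 1, and 1 of 8 tested in DESeq2.

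In all, 1340 genes changed with R5020 alone, 765 higher and 575 lower, with 75 at least 2-fold, of which 69 were higher. This count depended on single libraries: it was 826 without vehicle replicate 2, 867 without R5020 replicate 1 and 1659 without vehicle replicate 3.

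E2 and R5020 effects were set side by side because both were measured against the same vehicle libraries. Across 17753 genes, which are not independent replicates, the Pearson correlation of the log2 fold changes was 0.0984 and the Spearman correlation 0.0362. Simulated unchanged groups gave 0.519 and 0.457 on average over 100 draws, and the covariance was 0.00935 against 0.0179 simulated, a difference of -0.00852. Real effects widen the spread of the fold changes, which lowers a correlation even where the effects of the 2 hormones are unrelated. The simulated Pearson and Spearman values are therefore no yardstick, and the lower observed ones do not show opposed effects. Genes that rose with both hormones numbered 150, where 139.5 would be shared by independent lists, and genes that fell with both 129, against 91.2. Genes that rose with E2 and fell with R5020 numbered 214, against 104.8, and genes that fell with E2 and rose with R5020 numbered 257, against 121.3. Simulated unchanged groups shared at most 3 genes in any of these classes. Groups with no effect yield few calls, so that number is no yardstick for these overlaps. Leaving out vehicle replicate 1, 2 or 3 changed the correlation to 0.212, 0.186 and 0.232 and the genes that changed the same way from 279 to 163, 170 and 464; without R5020 replicate 1 they were 180. With DESeq2 the correlation was 0.442, and with the stricter filter it turned to -0.0219. These values rest on other sets of genes than the 17753. DESeq2 was run on every gene with a count in any library, and the stricter filter kept fewer genes. They are therefore not like for like with 0.0984. The simulation was run for the edgeR fit only. The vehicle libraries cannot be split into parts of at least 2 libraries each, so part of the overlap in the same direction may come from the shared controls. Shared controls move both effects the same way and do not favour the classes with opposite directions. The numbers for independent lists, however, take every gene as equally likely to be called. Genes with higher counts or less spread pass more easily in both comparisons, in any direction. Part of the excess in every class may come from that.

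**Figure D2:**
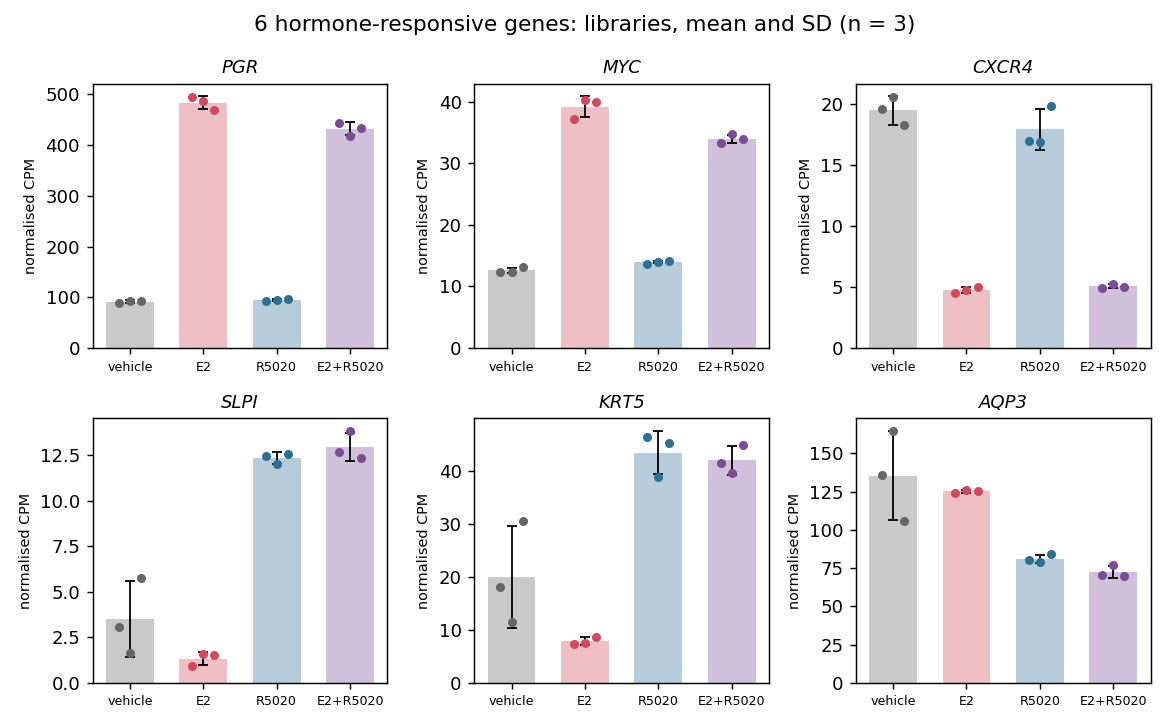
Normalised CPM of 6 genes named here, in the 4 groups; bars are means, error bars SDs (n = 3) and points libraries. PGR and MYC are higher and CXCR4 lower in both groups with E2, and SLPI and KRT5 are higher and AQP3 lower in both groups with R5020, with KRT5 at 7.82 CPM with E2 and 42.0 with E2+R5020.

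E2+R5020 vs E2 asks what R5020 changes in cells that also receive E2. R5020 raised KRT5 from 7.82 ± 0.759 to 42 ± 2.7 CPM (SD, n = 3), a log2 fold change of 2.42 ± 0.18 (SE; edgeR adjusted p = 3.10e-11). SLPI rose by 3.27 ± 0.22, ELFN2 by 3.47 ± 0.23, SERPINE2 by 2.96 ± 0.26, PCDH17 by 2.71 ± 0.21 and PKP1 by 2.59 ± 0.17. H19, an imprinted non-coding RNA that fell from 60 ± 2.31 to 30.6 ± 0.864 CPM, changed by -0.97 ± 0.06 and the entry H19_2 by -1.14 ± 0.12. The other largest falls were in XKR7 (-1.07 ± 0.14), IVL (-1.01 ± 0.11), AMPH (-0.96 ± 0.16) and ANO2 (-0.95 ± 0.12). FKBP5 rose by 0.36 ± 0.04, GREB1 by 0.20 ± 0.05 and CCND1 by 0.20 ± 0.03, while PGR (-0.16 ± 0.03), MYC (-0.21 ± 0.05) and MKI67 (-0.13 ± 0.04) fell; the MKI67 call was lost without E2 replicate 2, E2 replicate 3 or E2+R5020 replicate 1. ELF5 (0.01 ± 0.03), ESR1 (0.00 ± 0.04) and TFF1 (-0.92 ± 0.40) did not pass.

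Of 26 progestin receptor targets, 16 rose and 4 fell (17 and 5 adjusted over the list alone), F3 by 1.07 ± 0.06, SGK1 by 0.93 ± 0.06 and NET1 by 0.56 ± 0.04, with a median of 0.34. For progestin receptor targets the camera test gave adjusted p = 4.73e-15, and adjusted p = 0.0286 with an estimated correlation. Fatty acid and triglyceride genes rose in 8 of 20 cases and fell in 1 (9 and 1 adjusted over the list alone), ACSL1 by 0.73 ± 0.04, ELOVL5 by 0.39 ± 0.03 and SREBF1 by 0.34 ± 0.03. For fatty acid and triglyceride genes the camera test gave adjusted p = 2.40e-05, and adjusted p = 0.0286 with an estimated correlation. DNA replication and G1/S genes fell in 24 of 29 cases (26 adjusted over the list alone), CDC6 (-0.37 ± 0.05), MCM10 (-0.34 ± 0.04) and CDT1 (-0.31 ± 0.04) among them, with a median of -0.22. For DNA replication and G1/S genes the camera test gave adjusted p = 1.48e-15, but adjusted p = 0.124 with an estimated correlation. All 13 mitochondrially encoded mRNAs fell, also adjusted over the list alone, MT-ND6 (-0.51 ± 0.06), MT-ND1 (-0.43 ± 0.05) and MT-ATP8 (-0.37 ± 0.05) among them; the median was -0.28. For mitochondrially encoded mRNAs the camera test gave adjusted p = 1.33e-13, but adjusted p = 0.124 with an estimated correlation. These mRNAs took 11.0% ± 0.177 of counts with E2+R5020 and 13.1% ± 0.208 with E2 (SD, n = 3).

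Estrogen receptor targets fell in 13 of 28 cases and rose in 5 (15 and 5 adjusted over the list alone), STC2 (-0.54 ± 0.04), RARA (-0.34 ± 0.04) and CA12 (-0.28 ± 0.03) among those that fell. For estrogen receptor targets the camera test gave adjusted p = 8.95e-05, but adjusted p = 0.112 with an estimated correlation. Ribosome biogenesis genes fell in 8 of 18 cases and rose in 1, the same numbers adjusted over the list alone; NOLC1 (-0.26 ± 0.03), NCL (-0.22 ± 0.03) and NOP56 (-0.20 ± 0.03) fell. For ribosome biogenesis genes the camera test gave adjusted p = 0.0225, but adjusted p = 0.298 with an estimated correlation, and the list did not pass without E2+R5020 replicate 1. The ribosome biogenesis genes that fell numbered 4 without E2 replicate 3, E2+R5020 replicate 1 or E2+R5020 replicate 3 and among 18 tested in DESeq2, 3 without a filter and 5 with rDNA-repeat and mitochondrial genes left out. Cholesterol synthesis genes rose in 9 of 19 cases and fell in 1 (10 and 1 adjusted over the list alone), DHCR7 by 0.29 ± 0.04. For cholesterol synthesis genes the camera test gave adjusted p = 0.00362, but adjusted p = 0.298 with an estimated correlation. In steroid receptors and steroid metabolism 6 of 16 genes rose and 2 fell (7 and 2 adjusted over the list alone), CYP1A1 by 0.87 ± 0.10, SRD5A1 by 0.66 ± 0.05 and HSD11B2 by 0.45 ± 0.05. For steroid receptors and steroid metabolism the camera test gave adjusted p = 1.82e-04, but adjusted p = 0.124 with an estimated correlation. Apoptosis and survival genes rose in 6 of 18 cases and fell in 2 (7 and 2 adjusted over the list alone); BMF, which promotes cell death, rose by 1.20 ± 0.07, and CFLAR, which restrains it, by 0.33 ± 0.05. For apoptosis and survival genes the camera test gave adjusted p = 0.0219, but adjusted p = 0.112 with an estimated correlation. The gene that moved against the rest in each of the fatty acid, ribosome biogenesis and cholesterol lists was lost without E2+R5020 replicate 3. The estrogen receptor targets that rose numbered 3 without E2 replicate 3, and the steroid genes that fell 1 without E2 replicate 2.

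In all, 4205 genes changed with R5020 in the presence of E2, 2065 higher and 2140 lower, and 4378 without vehicle replicate 3. At least 2-fold changes were found in 213, of which 174 were higher. Of the 1340 genes called with R5020 alone, 1064 were also called here, 1060 in the same direction and 4 in the opposite one.

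**Figure D3:**
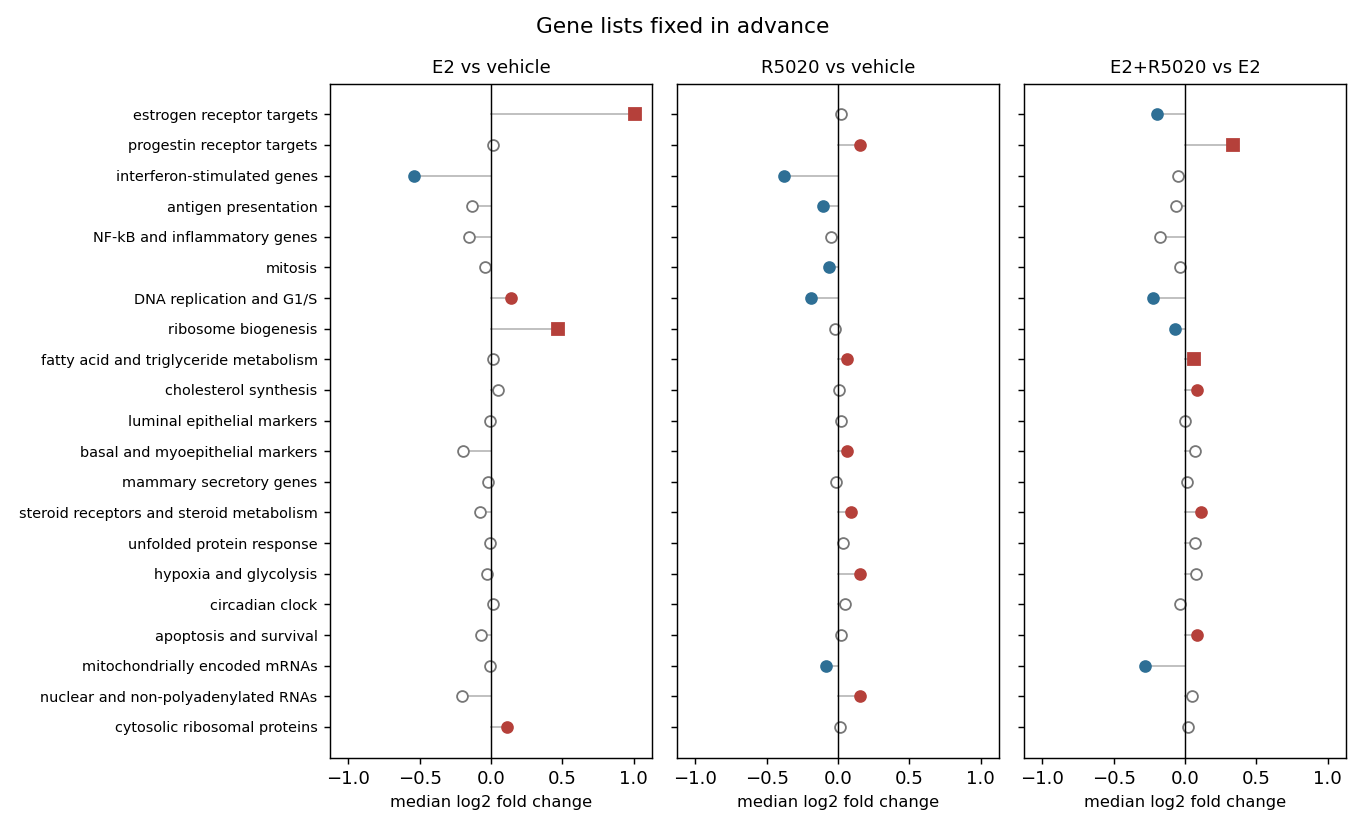
Median log2 fold change (x axis) of the tested members of 21 gene lists (y axis) in 3 comparisons. Filled symbols passed the camera test at the preset correlation, red for a positive and blue for a negative median, squares passed with an estimated correlation too, and open circles did not pass; estrogen receptor targets reach 1.01 with E2 and progestin receptor targets 0.34 with R5020 added to E2.

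E2+R5020 vs vehicle gives the joint effect of both hormones. The largest rises were in GATA4 (3.98 ± 0.31; SE, n = 3 per group), SPINK4 (3.83 ± 0.24), CHRM4 (2.96 ± 0.11), CXCL12 (2.95 ± 0.09), ACOT6 (2.49 ± 0.15) and SCNN1G (2.36 ± 0.14). The largest falls were in CHST1 (-2.67 ± 0.13), EDN2 (-2.36 ± 0.15), the potassium channel gene KCNC1 (-2.14 ± 0.06), CXCR4 (-1.94 ± 0.08), PCED1B (-1.92 ± 0.12) and LDLRAD1 (-1.86 ± 0.17). PGR rose by 2.24 ± 0.04, MYC by 1.43 ± 0.06, GREB1 by 1.29 ± 0.05, KRT5 by 1.06 ± 0.15, CCND1 by 0.62 ± 0.04, ESR1 by 0.36 ± 0.04 and FKBP5 by 0.27 ± 0.04. ELF5 (-0.40 ± 0.03) and MKI67 (-0.14 ± 0.04) fell, MKI67 not past the threshold without vehicle replicate 3 or E2+R5020 replicate 1, and TFF1 (0.06 ± 0.47) did not pass.

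Estrogen receptor targets rose in 22 of 28 cases and fell in 1 (22 and 2 adjusted over the list alone), RAPGEFL1 by 1.97 ± 0.04. For estrogen receptor targets the camera test gave adjusted p = 3.98e-58, and adjusted p = 3.41e-05 with an estimated correlation. The target that fell was lost without vehicle replicate 2 or E2+R5020 replicate 3, and with upper-quartile factors 2 fell. All 18 ribosome biogenesis genes rose, also adjusted over the list alone, RRP12 by 0.53 ± 0.04, NOP56 by 0.49 ± 0.03 and BOP1 by 0.46 ± 0.04. For ribosome biogenesis genes the camera test gave adjusted p = 3.54e-14, and adjusted p = 0.0132 with an estimated correlation. Progestin receptor targets rose in 16 of 26 cases and fell in 5, the same numbers adjusted over the list alone, SGK1 by 1.42 ± 0.07, KLF4 by 1.12 ± 0.06 and HSD11B2 by 0.82 ± 0.05. For progestin receptor targets the camera test gave adjusted p = 4.69e-07, but adjusted p = 0.131 with an estimated correlation. Hypoxia and glycolysis genes rose in 8 of 17 cases and fell in 3, the same numbers adjusted over the list alone, PFKFB3 by 1.33 ± 0.03, HK2 by 0.58 ± 0.05 and LDHA by 0.43 ± 0.03. For hypoxia and glycolysis genes the camera test gave adjusted p = 0.00171, but adjusted p = 0.391 with an estimated correlation. Cholesterol synthesis genes rose in 10 of 19 cases, the same number adjusted over the list alone, LSS by 0.35 ± 0.03, DHCR7 by 0.31 ± 0.04 and FDFT1 by 0.26 ± 0.03. For cholesterol synthesis genes the camera test gave adjusted p = 0.00611, but adjusted p = 0.391 with an estimated correlation. Cytosolic ribosomal protein genes rose in 16 of 19 cases, the same number adjusted over the list alone, RPS14 by 0.27 ± 0.04, RPS23 by 0.24 ± 0.04 and RPL10A by 0.20 ± 0.04. For ribosomal protein genes the camera test gave adjusted p = 0.00449, but adjusted p = 0.647 with an estimated correlation.

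In steroid receptors and steroid metabolism 6 of 16 genes rose and 4 fell (7 and 4 adjusted over the list alone), SRD5A1 by 0.60 ± 0.05. For steroid receptors and steroid metabolism the camera test gave adjusted p = 7.26e-05, but adjusted p = 0.149 with an estimated correlation. All 13 mitochondrially encoded mRNAs fell, also adjusted over the list alone, MT-ND6 (-0.49 ± 0.06), MT-ND4 (-0.37 ± 0.05) and MT-ATP8 (-0.37 ± 0.05) among them. For mitochondrially encoded mRNAs the camera test gave adjusted p = 3.14e-06, but adjusted p = 0.391 with an estimated correlation. Interferon-stimulated genes fell in 14 of 23 cases (15 adjusted over the list alone), IRF7 (-0.67 ± 0.12), DDX58 (-0.61 ± 0.12) and STAT2 (-0.43 ± 0.06) among them. For interferon-stimulated genes the camera test gave adjusted p = 0.00402, but adjusted p = 0.647 with an estimated correlation. Antigen presentation genes fell in 8 of 11 cases, the same number adjusted over the list alone, PSMB9 (-0.96 ± 0.14), TAPBP (-0.28 ± 0.03) and HLA-E (-0.18 ± 0.04) among them. For antigen presentation genes the camera test gave adjusted p = 0.0146, but adjusted p = 0.608 with an estimated correlation. Both of these lists failed the test without vehicle replicate 2, where 8 interferon-stimulated and 4 antigen presentation genes fell, and 6 of 23 interferon-stimulated genes tested fell in DESeq2. In all, 6965 genes changed, 3646 higher and 3319 lower, with 567 at least 2-fold. The split was 2884 higher and 4267 lower with upper-quartile factors, and 6372 genes changed without vehicle replicate 3.

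E2+R5020 vs R5020 asks what E2 changes in cells that also receive R5020. The largest rises were in GATA4 (3.64 ± 0.29; SE, n = 3 per group), SPINK4 (3.36 ± 0.22), CHRM4 (2.89 ± 0.11), CISH (2.25 ± 0.10), DISP3 (2.25 ± 0.14) and C8orf46 (2.24 ± 0.10), and the largest falls in CHST1 (-2.52 ± 0.13), TM4SF1 (-2.34 ± 0.15), LDLRAD1 (-2.09 ± 0.17), KCNC1 (-1.98 ± 0.06), EDN2 (-1.87 ± 0.16) and CXCR4 (-1.82 ± 0.08). PGR rose by 2.19 ± 0.04, MYC by 1.28 ± 0.05, GREB1 by 1.05 ± 0.05, CCND1 by 0.45 ± 0.04 and ESR1 by 0.24 ± 0.04. ELF5 (-0.38 ± 0.03) fell. FKBP5 (0.08 ± 0.04), KRT5 (-0.05 ± 0.14), MKI67 (-0.06 ± 0.04) and TFF1 (0.19 ± 0.47) did not pass.

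Estrogen receptor targets rose in 22 of 28 cases, the same number adjusted over the list alone, RAPGEFL1 by 1.76 ± 0.04 and CA12 by 1.10 ± 0.03. For estrogen receptor targets the camera test gave adjusted p = 2.93e-63, and adjusted p = 8.22e-06 with an estimated correlation. All 18 ribosome biogenesis genes rose, also adjusted over the list alone, NOP56 by 0.57 ± 0.03, RRP12 by 0.49 ± 0.03 and NOLC1 by 0.45 ± 0.03. For ribosome biogenesis genes the camera test gave adjusted p = 1.72e-19, and adjusted p = 0.00398 with an estimated correlation. DNA replication and G1/S genes rose in 17 of 29 cases (20 adjusted over the list alone), MCM10 by 0.38 ± 0.04, E2F1 by 0.30 ± 0.04 and UHRF1 by 0.23 ± 0.04. For DNA replication and G1/S genes the camera test gave adjusted p = 0.00165, but adjusted p = 0.564 with an estimated correlation. Progestin receptor targets rose in 13 of 26 cases and fell in 5 (13 and 6 adjusted over the list alone), KLF4 by 0.69 ± 0.05, HSD11B2 by 0.68 ± 0.05 and MT2A by 0.55 ± 0.04. For progestin receptor targets the camera test gave adjusted p = 0.00316, but adjusted p = 0.544 with an estimated correlation. Cholesterol synthesis genes rose in 11 of 19 cases (13 adjusted over the list alone), MSMO1 by 0.41 ± 0.06, SQLE by 0.34 ± 0.03 and LSS by 0.23 ± 0.03. For cholesterol synthesis genes the camera test gave adjusted p = 0.00568, but adjusted p = 0.544 with an estimated correlation. Cytosolic ribosomal protein genes rose in 14 of 19 cases (15 adjusted over the list alone), RPS23 by 0.22 ± 0.04, RPS14 by 0.21 ± 0.04 and RPL35 by 0.17 ± 0.04. For ribosomal protein genes the camera test gave adjusted p = 0.0118, but adjusted p = 0.715 with an estimated correlation; the call ended without E2+R5020 replicate 2, where 7 of these genes rose, and 9 rose with upper-quartile factors.

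In steroid receptors and steroid metabolism 4 of 16 genes rose and 4 fell, the same numbers adjusted over the list alone, SRD5A1 by 0.32 ± 0.05; the median of -0.10 and the mean of 0.04 differ in sign, and the list passed as higher. For steroid receptors and steroid metabolism the camera test gave adjusted p = 0.0437, but adjusted p = 0.544 with an estimated correlation; the call also ended without vehicle replicate 3, R5020 replicate 1 or R5020 replicate 3. Of 13 mitochondrially encoded mRNAs, 12 fell, the same number adjusted over the list alone, MT-ND6 (-0.43 ± 0.06), MT-ND5 (-0.28 ± 0.05) and MT-ATP8 (-0.26 ± 0.05) among them. For mitochondrially encoded mRNAs the camera test gave adjusted p = 0.00111, but adjusted p = 0.559 with an estimated correlation. In all, 6526 genes changed, 3449 higher and 3077 lower, with 430 at least 2-fold; with upper-quartile factors 2732 were higher and 3910 lower. Without vehicle replicate 3 the count was 6742. Of the 6053 genes called with E2 alone, 4292 were also called here, 4258 in the same direction.

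R5020 vs E2 sets the 2 hormones against each other. Higher with R5020 were TM4SF1 (3.53 ± 0.18; SE, n = 3 per group), SLPI (3.21 ± 0.22), ELFN2 (2.94 ± 0.24), PCDH17 (2.94 ± 0.20), SERPINE2 (2.61 ± 0.27) and KRT5 (2.48 ± 0.17). Lower were GATA4 (-4.33 ± 0.26), SPINK4 (-3.35 ± 0.22), CHRM4 (-2.66 ± 0.11), PHACTR1 (-2.49 ± 0.09), CISH (-2.47 ± 0.09), KCNF1 (-2.45 ± 0.10) and PGR (-2.35 ± 0.04). ELF5 (0.40 ± 0.03) and FKBP5 (0.28 ± 0.04) were higher with R5020, and MYC (-1.49 ± 0.05), GREB1 (-0.85 ± 0.05), CCND1 (-0.25 ± 0.04) and ESR1 (-0.23 ± 0.04) lower. TFF1, at -1.11 ± 0.41, passed at adjusted p = 0.0273 and was lost under 5 of the settings tried, and MKI67 (-0.07 ± 0.04) did not pass.

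Estrogen receptor targets were lower with R5020 than with E2 in 26 of 28 cases, the same number adjusted over the list alone, RARA (-1.56 ± 0.04) and CA12 (-1.38 ± 0.03) among them. For estrogen receptor targets the camera test gave adjusted p = 1.51e-67, and adjusted p = 7.64e-06 with an estimated correlation. All 18 ribosome biogenesis genes were lower, also adjusted over the list alone, NOP56 (-0.76 ± 0.03), NOLC1 (-0.71 ± 0.03) and WDR43 (-0.65 ± 0.04) among them. For ribosome biogenesis genes the camera test gave adjusted p = 1.48e-21, and adjusted p = 0.00267 with an estimated correlation. DNA replication and G1/S genes were lower in 28 of 29 cases, the same number adjusted over the list alone, MCM10 (-0.71 ± 0.04), CDC6 (-0.66 ± 0.05) and E2F1 (-0.60 ± 0.04) among them. For DNA replication and G1/S genes the camera test gave adjusted p = 8.63e-16, but adjusted p = 0.224 with an estimated correlation. Nuclear and non-polyadenylated RNAs were higher in 4 of 11 cases, the same number adjusted over the list alone, HIST1H2AC (0.82 ± 0.06), NEAT1 (0.77 ± 0.07) and HIST1H2BC (0.46 ± 0.08) among them. For nuclear RNAs the camera test gave adjusted p = 0.0309, but adjusted p = 0.543 with an estimated correlation, and the call ended without E2 replicate 2. In all, 7605 genes differed, 3744 higher and 3861 lower with R5020, and 649 at least 2-fold, of which 401 were higher. With upper-quartile factors 4256 were higher and 3363 lower. Without vehicle replicate 3 the genes that differed numbered 7760.

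The interaction asks whether R5020 had the same effect with E2 as without it; a positive value is a larger rise or a smaller fall with E2. KRT5 rose by 1.11 ± 0.15 with R5020 alone and by 2.42 ± 0.18 with R5020 added to E2, an interaction of 1.31 ± 0.24 (SE, n = 3 per group; edgeR adjusted p = 0.00258). F3, which encodes tissue factor, went from 14.1 ± 0.804 to 17.5 ± 0.819 CPM without E2 and from 11.2 ± 0.328 to 23.4 ± 0.724 CPM with it (SD, n = 3), an interaction of 0.75 ± 0.09 (adjusted p = 1.79e-05). Other positive interactions were those of ELFN2 (1.94 ± 0.34), PCDH17 (1.60 ± 0.28), SLPI (1.47 ± 0.31), FAM49A (0.89 ± 0.15) and AK7 (0.85 ± 0.15). Negative interactions were those of PPFIA4 (-1.04 ± 0.20), CXCL12 (-0.93 ± 0.12), NDUFA4L2 (-0.89 ± 0.21), NKAIN1 (-0.80 ± 0.13), ANO2 (-0.79 ± 0.17) and FGFBP2 (-0.75 ± 0.09), as well as MYC (-0.35 ± 0.08) and PGR (-0.22 ± 0.05). FKBP5 (0.18 ± 0.06), ELF5 (0.03 ± 0.05), CCND1 (0.02 ± 0.05), GREB1 (-0.04 ± 0.07), MKI67 (-0.05 ± 0.06), ESR1 (-0.12 ± 0.06) and TFF1 (-0.78 ± 0.63) did not pass. The calls of SLPI (without E2 replicate 1), MYC (without E2 replicate 2) and ANO2 (without R5020 replicate 1) each ended without a single library, and those of PGR and NDUFA4L2 without any 1 of 6 libraries.

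Estrogen receptor targets had a negative interaction in 7 of 28 cases (12 adjusted over the list alone), RARA (-0.32 ± 0.06) and SLC7A5 (-0.30 ± 0.05) among them, with a median of -0.18. For estrogen receptor targets the camera test gave adjusted p = 1.22e-11, and adjusted p = 0.0234 with an estimated correlation. The estrogen receptor targets with a negative interaction numbered 3 without E2 replicate 2 and 11 without vehicle replicate 2. Progestin receptor targets had a positive one in 6 of 26 cases and a negative one in 1 (11 and 2 adjusted over the list alone), NET1 (0.35 ± 0.06) and TSC22D3 (0.31 ± 0.05) among the positive. For progestin receptor targets the camera test gave adjusted p = 1.55e-08, but adjusted p = 0.0722 with an estimated correlation. Positive interactions of progestin receptor targets numbered 10 without vehicle replicate 2, 9 without a filter and 4 without E2 replicate 2 or R5020 replicate 2. The negative one was lost with DESeq2 size factors, with rDNA-repeat and mitochondrial genes left out, and without any 1 of 9 libraries, all but vehicle replicate 2, R5020 replicate 3 and E2+R5020 replicate 1. Of 13 mitochondrially encoded mRNAs, 3 had a negative interaction (10 adjusted over the list alone), MT-ND6 (-0.46 ± 0.09), MT-ND5 (-0.31 ± 0.07) and MT-ND1 (-0.30 ± 0.08), the last 2 lost under 6 and 11 of the settings tried. Without vehicle replicate 3, E2 replicate 2, E2 replicate 3, R5020 replicate 1, R5020 replicate 2 or E2+R5020 replicate 3, 1 of the 13 passed, and without R5020 replicate 3, 10 did; 9 passed without a filter, 5 in DESeq2 and 6 in limma-voom. For mitochondrially encoded mRNAs the camera test gave adjusted p = 1.37e-12, but adjusted p = 0.157 with an estimated correlation. Fatty acid and triglyceride genes had a positive interaction in 2 of 20 cases (5 adjusted over the list alone), ACSL1 (0.45 ± 0.06) and ELOVL5 (0.23 ± 0.05), while SREBF1 was at 0.17 ± 0.05. For fatty acid and triglyceride genes the camera test gave adjusted p = 0.00188, but adjusted p = 0.0722 with an estimated correlation. Fatty acid and triglyceride genes with a positive interaction numbered 5 of 17 tested in DESeq2, 4 without a filter, and 3 in limma-voom, without vehicle replicate 2 or with rDNA-repeat and mitochondrial genes left out. Cholesterol synthesis genes had one in 2 of 19 cases (6 adjusted over the list alone), while DHCR7 was at 0.19 ± 0.05. That count was 0 without E2 replicate 1, E2 replicate 2 or R5020 replicate 2, 1 without E2 replicate 3, R5020 replicate 1, E2+R5020 replicate 2 or E2+R5020 replicate 3, and 5 without R5020 replicate 3 or without a filter. For cholesterol synthesis genes the camera test gave adjusted p = 7.15e-05, but adjusted p = 0.185 with an estimated correlation.

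In apoptosis and survival 1 of 18 genes, BMF (0.65 ± 0.10), had a positive interaction (2 adjusted over the list alone, and 2 without vehicle replicate 2 or R5020 replicate 3), and CFLAR (0.14 ± 0.07) did not pass. For apoptosis and survival genes the camera test gave adjusted p = 0.00272, but adjusted p = 0.0722 with an estimated correlation. Of 17 luminal epithelial markers 1, AGR2 (-0.31 ± 0.06), had a negative interaction (6 adjusted over the list alone); GATA3 (-0.18 ± 0.05) and TFAP2C (-0.17 ± 0.05) did not pass. For luminal epithelial markers the camera test gave adjusted p = 0.00188, but adjusted p = 0.0722 with an estimated correlation. The luminal markers with a negative interaction numbered 3 without vehicle replicate 2, 2 of 16 tested in DESeq2, and 2 in limma-voom or without vehicle replicate 3, E2 replicate 2, R5020 replicate 3 or E2+R5020 replicate 2. Of 23 interferon-stimulated genes 1 had a positive interaction, also adjusted over the list alone; IFI6 (0.54 ± 0.23) and IRF7 (0.45 ± 0.18) did not pass. The number was 0 without E2 replicate 2, E2 replicate 3 or R5020 replicate 1, 0 of only 9 tested in DESeq2, 2 without E2 replicate 1 or R5020 replicate 3, 4 without vehicle replicate 3 and 8 without a filter. For interferon-stimulated genes the camera test gave adjusted p = 9.99e-06, but adjusted p = 0.588 with an estimated correlation. None of 25 mitosis genes passed in edgeR (1 was positive adjusted over the list alone), with CCNB1 at 0.19 ± 0.05, BUB1 at 0.11 ± 0.06 and KIF20A at 0.11 ± 0.06; the list passed at adjusted p = 0.0206, but not with an estimated correlation (adjusted p = 0.711) or without vehicle replicate 1, vehicle replicate 3, E2 replicate 1, R5020 replicate 1 or E2+R5020 replicate 2. Under other settings 1 mitosis gene passed: in DESeq2, with DESeq2 size factors, with the replicate block, without a filter, with rDNA-repeat and mitochondrial genes left out, and without vehicle replicate 2, R5020 replicate 3 or E2+R5020 replicate 1.

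In all, 269 genes had an interaction, 179 positive and 90 negative, 11 of them of at least 2-fold. Without a filter the count was 531. The split was 262 and 80 with rDNA-repeat and mitochondrial genes left out, and 213 and 61 without vehicle replicate 3. The count was 178 without vehicle replicate 1, 475 without vehicle replicate 2, 148 without E2 replicate 2, 175 without E2 replicate 3, 166, 150 and 579 without R5020 replicates 1, 2 and 3, and 173 without E2+R5020 replicate 3.

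Lists that passed the camera test in none of the 7 comparisons were tested with the others. With E2, NF-kB and inflammatory genes rose in 3 and fell in 3 of 12 cases (camera adjusted p = 0.248), mammary secretory genes in 3 and 2 of 7 (adjusted p = 0.784), unfolded protein response genes in 5 and 6 of 18 (adjusted p = 0.883) and circadian clock genes in 3 and 4 of 15 (adjusted p = 0.59); adjusted over the list alone, the falls were 3, 2, 6 and 5 and the rises unchanged. For the circadian clock list the median of 0.01 and the mean of 0.05 were above 0 and the camera test's direction was down. By fry the NF-kB list was lower with E2 (adjusted p = 3.52e-04). The mammary secretory, unfolded protein response and circadian lists did not pass fry with E2 (adjusted p = 0.105, 0.916 and 0.0571). Fry also passed some of these lists in other comparisons. Of 17 stromal, endothelial and immune markers in the table, 4 passed the filter, too few for a test; the most abundant, COL1A1, was at 55.3 ± 1.6 CPM in vehicle.

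On GRCh38, PGR spans chromosome 11, 101029624 to 101130524, GATA4 chromosome 8, 11676959 to 11760002, CXCL12 chromosome 10, 44370165 to 44386493, CXCR4 chromosome 2, 136114349 to 136118165, SLPI chromosome 20, 45252239 to 45254564, KRT5 chromosome 12, 52514575 to 52520687, KRT4 chromosome 12, 52806549 to 52814551, AQP3 chromosome 9, 33441154 to 33447633 and F3 chromosome 1, 94529225 to 94541800; each is a protein-coding gene. The annotated exons of these genes overlap no other annotated exon, except for PGR, where 5.27% of the exonic length overlaps PGR-AS1 on the opposite strand. Other named genes share more. On the same strand, 62.2% of the exonic length of NUSAP1, 42.3% of ALDOA, 22.2% of MT-ATP8 and 13.3% of FGFBP2 overlap another gene. On the opposite strand, the shares are 27.7% for ACOT6, 23.6% for MCM2, 20.6% for PSMB8, 17.9% for RARA, 15.9% for FOXM1, 14.1% for DISP3, 13.7% for PCED1B, 13.3% for ALDOA, 12.1% for PHACTR1, 10.3% for CCND1 and 10.1% for CFLAR. The counts of these genes are uncertain.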

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

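The tests of the splits for the interaction, of R5020 exposure, of a swapped library and of mitochondrial rRNAs were chosen after the results they bear on had been seen. The others, except the splits of pairs of groups, were chosen after the data were first examined but before their own values were seen.

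The effect of R5020 differed between cells with and without E2 by an interaction test for 269 genes. With the average effects of E2 and of R5020 removed from log2 CPM, limma called 281 genes for the real split of the 12 libraries. Of 100 splits into 4 groups of 3, 1, the real one, gave as many. The highest of the others gave 186, and 13 of them gave any. In the other splits the interaction itself adds to the spread within groups, which lowers their counts. The test therefore cannot exclude chance. Of the list medians that passed at the preset correlation, only that of estrogen receptor targets also passed with an estimated one (adjusted p = 0.0234, against 0.0722 to 0.711 for the other 8). The medians were -0.18 for estrogen receptor targets, 0.17 for progestin receptor targets, 0.42 for interferon-stimulated genes, 0.0558 for mitosis, 0.0251 for fatty acid and triglyceride metabolism, 0.0525 for cholesterol synthesis, -0.071 for luminal epithelial markers, 0.10 for apoptosis and survival and -0.20 for mitochondrially encoded mRNAs. Reported genes with a positive interaction were ELFN2 (1.94), PCDH17 (1.60), SLPI (1.47), KRT5 (1.31), FAM49A (0.89), AK7 (0.85), F3 (0.75), BMF (0.65), ACSL1 (0.45), NET1 (0.35), TSC22D3 (0.31) and ELOVL5 (0.23), on the log2 scale. Those with a negative one were PGR (-0.22), SLC7A5 (-0.30), MT-ND1 (-0.30), MT-ND5 (-0.31), AGR2 (-0.31), RARA (-0.32), MYC (-0.35), MT-ND6 (-0.46), FGFBP2 (-0.75), ANO2 (-0.79), NKAIN1 (-0.80), NDUFA4L2 (-0.89), CXCL12 (-0.93) and PPFIA4 (-1.04).

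The R5020 response was larger in cells that also received E2: the noise-corrected slope of the effect with E2 on that without was 1.58 (jackknife SE 0.499), and the ratio of mean effects was 1.669 (SE 0.197) in rising and 1.69 (SE 0.317) in falling genes. A ratio above 1 also arises where E2 moves only the level without R5020. KRT5 is such a gene: against vehicle its log2 fold change was -1.36 with E2, 1.11 with R5020 and 1.06 with both. A general gain in responsiveness, which needs both ratios above 1, met that test at 1.669, but the test cannot decide for it. It is an average over genes: the mean effect was smaller with E2 than without for interferon-stimulated (-0.0292 and -0.361), mitosis (-0.0096 and -0.0566), antigen presentation (-0.144 and -0.203), hypoxia and glycolysis (0.0561 and 0.135), mammary secretory (0.0077 and 0.045), nuclear RNA (0.0050 and 0.115) and ribosomal protein genes (0.0255 and 0.0294, hardly apart). Of these, the first 2 lists passed the interaction test, neither with an estimated correlation. The mean effect changed sign for estrogen receptor targets (-0.170 with E2 and 0.0222 without), NF-kB (0.0098 and -0.0050) and cholesterol synthesis genes (0.0916 and -0.00027). It did so too for luminal (-0.0597 and 0.0099), circadian (-0.105 and 0.0191) and apoptosis genes (0.0660 and -0.0338). Without E2 these means lay near 0, where a sign is uncertain. The NF-kB and circadian lists did not pass the interaction test. Vehicle replicate 3 could also lower the effect measured without E2; without it the slope was 1.277 (SE 0.346), within 1 SE of 1, and the ratios were 1.486 (SE 0.183) and 1.315 (SE 0.242), so this explanation cannot be told apart from the gain on the slope, whose error is too wide. That E2 raised PGR, the receptor of R5020, gives a biological hypothesis that was not tested.

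Vehicle replicate 3 lay nearer to the R5020 libraries on PC2 (4.27) than vehicle replicates 1 and 2 did (12.7 and 19.8). It was not the only vehicle library that differed. On PC3, with 6.70% of the variance, replicate 2 was at 19.8, against 2.41 and -2.21 for replicates 1 and 3. A swap with an R5020 library is argued against, since the lowest R5020 library had a score of 0.1995 on the axis from E2 to E2+R5020 and vehicle replicate 3 one of -0.0982. Its deviation from the other 2 vehicle libraries scored 0.245 in rising and 0.1878 in falling genes on that axis, against 0.0381 and 0.0448 on the E2 axis, as R5020 exposure or admixture of RNA from an R5020 library would give. Vehicle replicate 2 deviated the other way, by -0.221 and -0.192, and replicate 1 by -0.0237 and 0.00431. Each deviation is taken from the other 2 vehicle libraries, so the deviations cancel out and some had to be of opposite sign. The vehicle libraries scored -0.256, -0.388 and -0.0982 on the axis, all between the E2 libraries, the highest at -0.571, and the R5020 libraries. Both a spread among vehicle libraries and an exposure stay open, and a difference between cultures was not tested.

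Mitochondrially encoded mRNAs were lower with E2+R5020 than with E2, by a median of -0.28. Fewer mitochondria, or a lower recovery of their RNA, would also lower the rRNAs of the same genome. These were at -0.04245 (SE 0.0509) for MT-RNR1 and -0.0298 (SE 0.0477) for MT-RNR2. That argues against this explanation only if their reads follow the amount of rRNA, which rRNA depletion or poly(A) selection would upset. The normalization is argued against by a median of -0.2697 with rDNA-repeat and mitochondrial genes left out of it. A joint fall of nuclear genes of oxidative phosphorylation is argued against by their median of 0.09636 (SE 0.018), with 21 of 47 tested genes higher and 1 lower. This SE is taken across genes, which are not independent, and does not measure the spread between libraries. The list of 55 was written after the data were first examined and before these values were seen. A change in the making or stability of these mRNAs may remain as a hypothesis and was not tested.

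For pairs of groups, 3 libraries against 3 allow 10 splits, too few for a share under 0.05. The real split gave 6053, 1340, 6965, 4205, 6526 and 7605 genes, for E2, R5020 and E2+R5020 against vehicle, E2+R5020 against E2 and against R5020, and R5020 against E2, and the highest other split gave 0, 3, 0, 0, 0 and 0. Every other split mixes libraries of both groups, which puts the hormone effect into the spread within groups. Few calls follow from that alone, so these numbers do not bear on chance.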

How the results depend on the processing

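Added after seeing the data were the removal of rDNA-repeat and mitochondrial genes, and upper-quartile factors for gene lists; the other settings were fixed before. Of 56 list calls 11 held under every setting and 45 were lost with an estimated correlation, and of 260 calls of named genes 240 held and 20 were lost under at least 1; no called list or gene changed direction. The removal gave no value for the mitochondrial list. The replicate number as a block gave 6149, 1427, 7067, 4330, 6611, 7681 and 343 genes and ended no call of a list or named gene. Of 18 same-numbered pairs 0 correlated above 0.1 (-0.045 to 0.0815), but pairs with different numbers also reached only 0.0870. The libraries that correlated best with their own number were 6 of 12. Pairing by number was thus neither shown nor excluded. Without 1 library, counts ran from 5101 to 6146 for E2 vs vehicle, 826 to 1659 for R5020 vs vehicle (867 without R5020 replicate 1), 5903 to 7069 for E2+R5020 vs vehicle, 3244 to 4510 for E2+R5020 vs E2, 5381 to 6800 for E2+R5020 vs R5020, 6584 to 7892 for R5020 vs E2 and 148 to 579 for the interaction. In that order, passing lists ran from 4 to 6, 10 to 12, 10 to 11, 9 to 11, 7 to 9, 3 to 5 and 8 to 12.

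At adjusted p under 0.01 counts fell to 693 for R5020 vs vehicle, 2785 for E2+R5020 vs E2 and 105 for the interaction, and at 2-fold to 430, 75, 567, 213, 430, 649 and 11, by the stricter threshold itself. Without a filter the interaction count was 531. With an estimated correlation 2, 0, 2, 2, 2, 2 and 1 lists passed, where 5, 11, 10, 9, 8, 4 and 9 had. Fry passed 6 for R5020 vs vehicle, 14 for E2+R5020 vs E2, 14 for E2+R5020 vs R5020 and 11 for R5020 vs E2. Of the 56 list calls fry lost 11. It lost interferon-stimulated genes in every comparison that called them (fry adjusted p = 0.0975 to 0.545). For R5020 vs vehicle it also lost antigen presentation (0.123), mitosis (0.185), mitochondrial mRNAs (0.217) and nuclear RNAs (0.185). The others were ribosomal protein genes for E2 vs vehicle (0.0571) and, for the interaction, mitosis (0.545) and mitochondrial mRNAs (0.0787). It kept every call of DNA replication and G1/S genes (0.0063 or below). The correlation of E2 and R5020 effects was 0.442 with DESeq2, over every gene with a count in any library. It reversed to -0.0219 with the stricter filter, over fewer genes. It ran from 0.0849 to 0.232 without 1 library (0.212, 0.186 and 0.232 without vehicle replicates 1, 2 and 3). The overlap of calls ran from 163 to 464 (170 without vehicle replicate 2, 180 without R5020 replicate 1). The cause of these moves was not tested.

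The genes that changed sign were all below the threshold. Without 1 library, the log2 value of MKI67, E2 vs vehicle, ran from -0.0768 to 0.0464, and that of ELF5, R5020 vs vehicle, from -0.0322 to 0.00615. That of TFF1, R5020 vs vehicle, ran from -1.48 to 0.262, of TFF1, E2+R5020 vs vehicle, from -0.0642 to 0.186, and of TFF1, E2+R5020 vs R5020, from -0.202 to 1.54. That of ESR1, E2+R5020 vs E2, ran from -0.0243 to 0.0354, of GREB1, interaction, from -0.106 to 0.0255, of MKI67, interaction, from -0.0961 to 0.0162, and of TFF1, interaction, from -1.18 to 0.563. ESR1, E2+R5020 vs E2, was -0.00954 with upper-quartile factors. The cause was not tested. Depth limits TFF1, with at most 20 counts in a library.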
